A study of Zea mays with 6 samples.

How the data were processed

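The data are 6 Affymetrix maize arrays hybridized with biotin-labelled cRNA made from total RNA of mesocotyls, 2 arrays for each of control, GA3 and UCZ. The values used are the signal intensities deposited by the authors, 1 per probe set and array, on a linear scale. Per the submitters' processing notes they were made with GCOS and MAS5; versions and settings are not given in the sources used here. The mean of each array, after trimming 2% of probe sets on each side, was 499.9, so the deposited intensities had been scaled to a common mean. The doses, the times of treatment and the solvent are not given in the sources used here. The labels call the arrays biological replicates and the design text names independent experiments.

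The table holds 17734 probe sets. The 113 control probe sets of the manufacturer were left out, which leaves 17621, and 66 reporter probe sets for foreign genes were kept in the table, of which 1 passed the filter. Gene names came from the platform annotation through gene identifiers, which name 1 gene for 1452 probe sets, several for 1 and none for 16168. Probe sets with several genes or none were tested but not named. The named probe sets stand for 1108 genes, of which 1060 were found in the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, used for names only, and 974 had a name other than a LOC number. Most probe sets are therefore unnamed here, and the gene groups cover only the named part.

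Signals were transformed to log2(signal + 16), and the 60% of probe sets with the highest mean over all arrays were kept (10573; lowest mean log2 value 6.96). Fold changes are on this scale, which understates the change of dim genes. A linear model of group means with a variance prior that follows the mean signal (limma 3.58.1 in R 4.3.3, lmFit and eBayes with trend) was fitted to all 6 arrays, so that the groups share 1 estimate of the spread (3 residual and 4.52 prior degrees of freedom). The tests of the 3 comparisons were two-sided. These and the F test were adjusted by Benjamini-Hochberg over the probe sets kept, with a threshold of 0.05. A count of probe sets that changed at least 2-fold in all 4 array pairs was made without a test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

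The numbers 1 and 2 occur in each group, and the design text names independent experiments, so the numbers were taken to pair the arrays. Deviations from the group means correlated across probe sets at 0.664 for control with GA3, 0.724 for control with UCZ and 0.755 for GA3 with UCZ, and the second principal component separated the numbers. The fit with the number as a block (2 residual and 11.7 prior degrees of freedom) was an alternative, and its values are given where they change the call of a gene or list, or move a count by more than 1.5 times.

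Genes were grouped into 35 lists by patterns on their symbols and synonyms, and 22 lists with at least 3 measured genes were tested with camera (inter-gene correlation 0.01) on the brightest probe set of each of 819 named genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera has only the residual degrees of freedom, 3 or, with the block, 2. Its power is therefore low, and a list that misses the threshold under it is not shown to be unchanged. Some patterns caught wrong genes or missed members, and corrected lists were an alternative chosen after the matched names were seen. The genes named in each comparison were, by rule, the 10 largest rises and 10 largest falls among called probe sets of 1 characterized gene that went the same way in all 4 array pairs, the 3 members with the smallest p of each called list, and every measured gene of gibberellin synthesis, inactivation and perception. Further members of lists, LOC genes and the genes with opposite changes were named after their values were seen. The test, the filter, the lists, the naming rule and the alternatives, except those said to be chosen later, were fixed before the data were examined.

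The steps were tested on simulated data of 10573 probe sets for UCZ versus control. Known changes of 1.5-, 2- and 4-fold were set into 67, 67 and 66 of them. Without the block the fit recovered 2.99% of 1.5-fold, 37.3% of 2-fold and 95.5% of 4-fold changes, and 0% of its 90 calls were false. With the block it recovered 88.1% of the 1.5-fold and all of the larger changes, with 7.69% of 208 calls false. The simulated noise had the spread of the blocked fit, with a replicate effect common to the groups added. That setting favours the block, so the gain over the fit without it was built in. No probe set was called in the simulated, unchanged GA3 group, and the 1 list that had been shifted was called.

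Alternatives were median centring, quantile normalization, adding 1 or 64 in place of 16, no filter, the brightest 40% of probe sets, a variance prior without a trend or robust, only the 2 groups compared, the replicate block alone and with quantile normalization, a threshold of 0.10, a 1.5-fold rule, all probe sets of a gene, leaving out each array in turn, scaling to the 12 poly-A control probe sets, and comparisons with no control array in common. Responses to GA3 and UCZ were compared by the correlation and covariance of their log2 changes, beside 100 simulations of unchanged groups set against the same controls. Groups of 2 arrays allow no test for outlying arrays and no count of other splits. The fits that leave out 1 array had no block. They leave 1 group with a single replicate number, so part of the difference between replicate numbers enters the changes of that group.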

Results

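Transcript levels were measured in the mesocotyl, the stem segment of a grass seedling that lifts the shoot towards the soil surface, of maize plants harvested 10 days after sowing at a depth of 20 cm in the dark. The plants were controls, or had received the gibberellin GA3, or had received UCZ, which the series describes as an inhibitor of gibberellin biosynthesis. Each group had 2 arrays that the labels call biological replicates, giving 6 Affymetrix arrays, and this number of arrays limits the precision of every value. The median signal of replicates 1 and 2 was 199.6 and 203.2 in control, 201.4 and 195.6 in GA3, and 189 and 183.1 in UCZ. The actin 3′/5′ signal ratio, a measure of RNA integrity, was 3.57 and 2.76 in control, 4.64 and 3.4 in GA3, and 4.14 and 3.11 in UCZ. Across the 10573 probe sets kept, which are not independent replicates, the first principal component (43.7% of the variance) separated UCZ from the other groups. The second (33.4%) separated replicate 1 from replicate 2. The third (15.2%) separated GA3 (−14.03 and −16.93) from control (16.01 and 12.45). Arrays of 1 group correlated at r = 0.9624 in control, 0.9613 in GA3 and 0.965 in UCZ, while control and GA3 arrays of the same replicate number correlated at 0.9707 and 0.9726. At least 1 group differed for 1683 probe sets (limma F test, adjusted p under 0.05), or 4048 with the replicate number as a block. Without UCZ replicates 1 and 2 the F test called 710 and 584, and without control replicates 1 and 2 it called 1046 and 995.

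The probe sets for the bacterial poly-A control transcripts, which in this array system are added to the RNA before labelling, were brighter on the UCZ arrays than on the control arrays by a log2 difference of 0.62 in replicate 1 and 0.67 in replicate 2 (SD over 12 probe sets, 0.186 and 0.141). The GA3 arrays differed from control by −0.0225 and −0.235. Scaling every array to these controls, an alternative chosen after they were seen, moved the median log2 change of all probe sets from −0.026 to −0.67 in UCZ versus control, from 0.040 to 0.81 in GA3 versus UCZ, and from 0.018 to 0.15 in GA3 versus control. Changes below are therefore relative to the deposited scaling, in which the median probe set moved by at most 0.0402. The poly-A controls also differed between replicates 1 and 2. Their mean log2 was 8.374 and 8.0578 in control, 8.3515 and 7.8232 in GA3, and 8.9905 and 8.7228 in UCZ. Scaling puts these differences into every probe set, and the fit without the block counts them as spread. A call lost under that scaling can therefore come from added spread and need not mean a smaller change.

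The first comparison asked which transcripts responded to added gibberellin. Expansins, proteins that loosen the cell wall, included the largest rise: expB7 rose from a signal of 614.6 ± 151 in control to 2549 ± 34.9 in GA3 (SD, n = 2), which is 4.13-fold (log2 2.04, SE 0.2, adjusted p = 0.0033). The expansin expB6 rose 2.07-fold, from 603.9 ± 23.5 to 1270 ± 131 (adjusted p = 0.012). The pathogenesis-related gene pr5, which encodes a thaumatin-like protein, fell from 1891 ± 225 to 308 ± 43.8, a 5.89-fold difference (log2 −2.56, SE 0.15, adjusted p = 0.00083). The chitinase gene chn1 fell from 4070 ± 103 to 1802 ± 153 (adjusted p = 0.003), and prp4, which carries the synonym PR-1, fell from 341.6 ± 83.2 to 97.54 ± 16.2 (adjusted p = 0.012).

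Among the other named genes that rose, phytase1 went from 380.2 ± 31.8 to 1081 ± 12, and pip2f, a plasma membrane aquaporin that conducts water, rose 2.46-fold from 364.4 ± 10.5. The gene piip1 rose 2.85-fold to 2869 ± 312, mlg3 2.95-fold to 310.1 ± 71.1, and dhn1, the dehydrin RAB17, 2.26-fold to 1764 ± 73. Smaller rises were those of pdc3, a pyruvate decarboxylase of fermentation (1.64-fold), and cpi2, a cystatin that inhibits cysteine proteases (1.54-fold). The adjusted p of these 7 genes lay between 0.0029 and 0.045. Among those that fell, sps1, a sucrose phosphate synthase, went from 359.5 ± 3.53 to 115.8 ± 12.1, me3, an NADP-malic enzyme, from 1810 ± 3.6 to 835.3 ± 60.3, and f3h, the flavanone 3-hydroxylase of flavonoid synthesis, from 568.9 ± 54.1 to 267.6 ± 38.7. The genes nthr3, aprl1 and AGA3b fell by log2 values of −1.19, −1.10 and −0.98, and the adjusted p of these 6 genes lay between 0.0056 and 0.032. The largest fall of all, −3.56, was that of a gene known only as LOC100125656.

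By gene list, 2 of the 9 measured expansins rose and 7 did not pass, against 6 that rose when adjusted over the list alone and 6 with the block, with a median log2 change of 0.625. The expansin list stood above the other genes (camera adjusted p = 1.94e-05; adjusted p = 0.512 with an estimated correlation). Its member expA3 had a log2 change of 1.13 that missed the threshold (adjusted p = 0.062; 0.00027 with the replicate block). Of 12 leaf photosynthesis genes, a list fixed as a marker of another tissue, 2 fell (me3 and pdk1) and 10 did not pass, against 8 that fell when adjusted over the list alone and 6 with the block, with a median of −0.33 (camera adjusted p = 7.88e-07; adjusted p = 0.512 with an estimated correlation). All 12 were below 0 under every scaling, although none was called under poly-A control scaling, where the median was −0.20. The carboxylase pep1 of the C4 pathway, with a log2 change of −0.57, missed the threshold (adjusted p = 0.072; 0.0021 with the block), and of the 3 other probe sets of pdk1, pyruvate phosphate dikinase, 2 went the same way. The other-tissue genes with no list test had log2 changes of −0.29 for pht1 (root), 0.13 for gz27 (kernel), and −0.69 and 0.77 for m19 and M2 (reproductive), none called, although m19 and M2 passed with the block (adjusted p = 0.0056 and 0.011). The defence list, as fixed, held 1 faller, chn1, among 5 genes, and 2 with the block (camera adjusted p = 0.444); none was called under poly-A control scaling, and the list did not hold pr5 and prp4. Lignin and phenylpropanoid genes had no called member of 5 (2 lower with the block) and a median of −0.38 (camera adjusted p = 0.0585; 0.0493 with the block; adjusted p = 0.512 with an estimated correlation, 0.48 with the block), or −0.26 under poly-A control scaling.

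In all, 140 probe sets passed, 51 higher and 89 lower in GA3 (36.4% higher, 52.6% under poly-A control scaling, which called 78), of which 35 and 61 differed at least 2-fold. At an unadjusted p under 0.05 there were 1282, and 29 of the 969 named probe sets tested were called. The block raised the count to 866 (327 higher, 539 lower), including all 140. Values of the groups did not overlap for 40.1% of probe sets, against 33.3% for exchangeable arrays. Since arrays of the same number deviated together, the share expected by chance is below 33.3%, here and in the comparisons below. Counts between replicate numbers hold that shared difference (here 72 higher and 4 lower in replicate 2) and are not noise alone. In all 4 array pairs 73 changed at least 2-fold, against 76 between replicate numbers. The count fell to 51 and 56 without control replicates 1 and 2, and to 77 and 67 without GA3 replicates 1 and 2. Of the 19 named genes called, 5 (chn1, pr5, piip1, phytase1 and expB7) passed in each fit that left out 1 array, 14 missed the threshold in at least 1, and 9 missed it under poly-A control scaling.

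**Figure D1:**
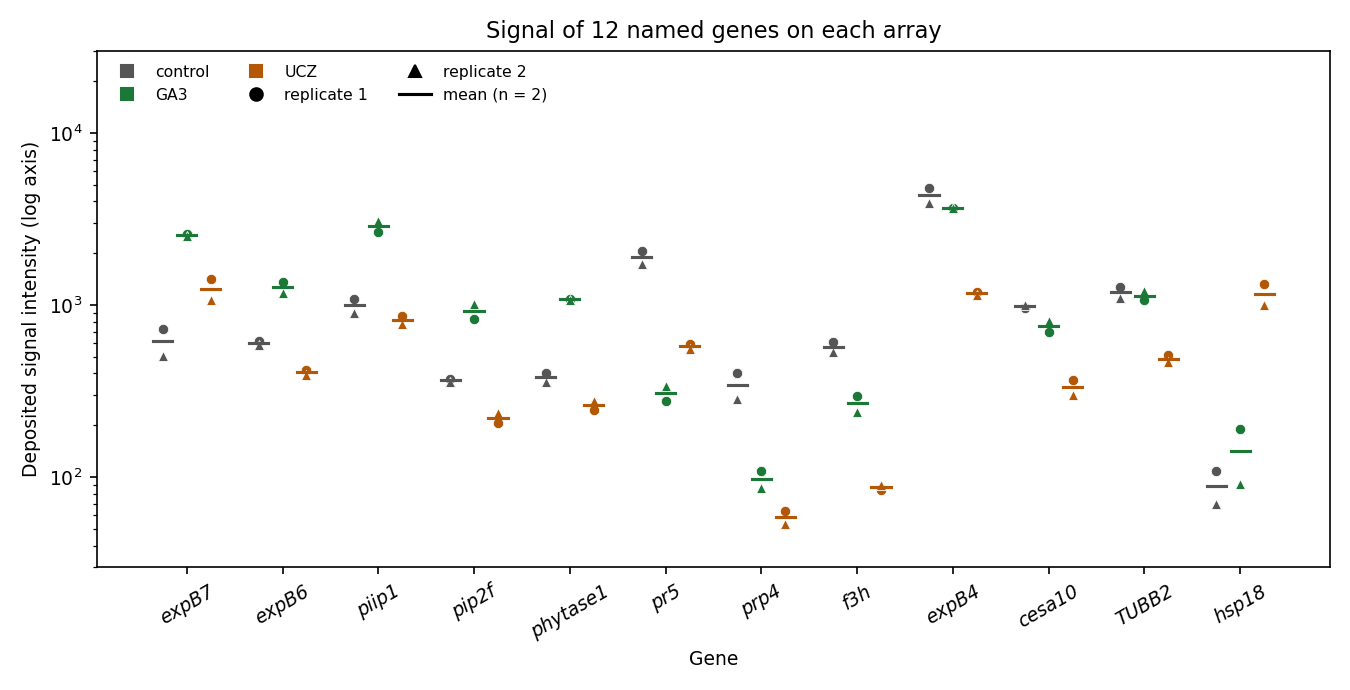
Deposited signal intensity (log axis) of 12 named genes on each array, with circles for replicate 1, triangles for replicate 2, colours for control, GA3 and UCZ, and lines for the means of 2 arrays. GA3 arrays stand above control arrays for expB7 (mean 2549 against 614.6) and phytase1 (1081 against 380.2), and UCZ arrays stand below them for expB4 (1167 against 4330) and above them for hsp18 (1160 against 88.58).

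The second comparison asked what the inhibitor of gibberellin synthesis changed. The small heat shock gene hsp18 rose from 88.58 ± 27.3 in control to 1160 ± 223 in UCZ (SD, n = 2), which is 11.3-fold (log2 3.50, SE 0.33, adjusted p = 0.0011). The expansin expB4 fell from 4330 ± 611 to 1167 ± 36.3, 3.66-fold (log2 −1.87, SE 0.12, adjusted p = 0.00028). The flavonoid gene f3h fell 5.66-fold, from 568.9 ± 54.1 to 87.23 ± 3.89 (adjusted p = 0.00025). The cellulose synthase gene cesa10, which belongs to the secondary-wall enzymes, fell from 981.4 ± 27.1 to 333.3 ± 47.7 (adjusted p = 0.0014), and the beta-tubulin TUBB2 from 1182 ± 118 to 486.2 ± 31.7 (adjusted p = 0.0023).

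Further falls were those of wip1, a wound-induced protease inhibitor (4176 ± 396 to 1443 ± 70.9), ACO31, an ACC oxidase that makes ethylene (1346 ± 229 to 423.8 ± 7), Lsi6, a silicon transporter (754.8 ± 141 to 237.2 ± 93), and saf1, which carries the synonym In2-1 (291.4 ± 10 to 69.57 ± 24.9). The genes pr5, prp4 and AGA3b had log2 changes of −1.69, −2.25 and −2.08. These falls had adjusted p values between 0.00044 and 0.012. Among the genes that rose, betl4, named for the basal endosperm transfer layer, went from 75.26 ± 22.1 to 279 ± 20.1, GLN6, a glutamine synthetase, from 485.9 ± 127 to 1228 ± 332, and AGP2, an ADP-glucose pyrophosphorylase subunit of starch synthesis, from 262.5 ± 47.4 to 597.6 ± 111 (adjusted p from 0.003 to 0.02). The gene tha9 rose 2.12-fold (adjusted p = 0.044), expB7 2.01-fold (adjusted p = 0.016) and aldh2, an aldehyde dehydrogenase, 1.92-fold (adjusted p = 0.018). The largest fall of all, −4.30, was that of a gene known only as LOC541622.

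Of 10 heat shock and chaperone genes, 5 rose (hsp18, hsp18f, hsp22, hsp101 and hsp18a), with 7 when adjusted over the list alone and a median of 0.65, but under poly-A control scaling the median was 0.012, with 2 higher and 2 lower. The list stood above other genes (camera adjusted p = 0.00372; adjusted p = 0.371 with an estimated correlation); hsp18f went from 75.59 ± 8.16 to 422 ± 85.7 and hsp22 from 73.91 ± 5.21 to 220.1 ± 18.4. Of 14 genes on the list named tubulins and actins, 5 fell and 9 did not pass, with 7 falling when adjusted over the list alone. The list holds tubulins, profilins and actin-depolymerizing factors, but no actin gene. Its median was −0.41 (camera adjusted p = 0.00372, or 0.371 with an estimated correlation). Under poly-A control scaling 8 fell and the median was −1.05. The tubulins tub5 and tua6 fell by log2 values of −0.78 and −0.73. Of 10 cellulose synthesis genes, 4 fell, namely the secondary-wall synthases cesa10, cesa11 and CesA12 (log2 −1.52, −1.36 and −1.32) and bk2 (−1.19), the brittle stalk gene, with 5 falling when adjusted over the list alone, 6 falling and 1 rising with the block, and a median of −0.30 (camera adjusted p = 0.029; adjusted p = 0.371 with an estimated correlation). That median was −0.19 with median centring and −0.94, with 8 falling, under poly-A control scaling. Expansins did not pass as a list (camera adjusted p = 0.158), with expB7 higher, 3 members lower (5 with the block) and a median of −0.55, against none higher, 7 lower and −1.20 under poly-A control scaling. Aquaporins had 5 members lower of 18, and 9 with the block (camera adjusted p = 0.0663; 0.0473 with the block; adjusted p = 0.371 with an estimated correlation, 0.656 with the block), led by tip2a of the vacuolar membrane with −1.42; poly-A control scaling gave 10. The leaf photosynthesis list, from another tissue, had 1 member lower, me3, of 12 (1 higher and 2 lower with the block) and a median of 0.089 that was 0.195 with median centring, −0.009 with quantile normalization and −0.55 under poly-A control scaling (camera adjusted p = 0.673 as deposited). The other-tissue genes pht1, gz27, m19 and M2 had log2 changes of −0.19, 0.36, −0.32 and −0.46, none called.

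In all, 1629 probe sets passed, 681 higher and 948 lower in UCZ (41.8% higher, of which 92 and 306 at least 2-fold). The higher share was 60.9% with median centring (1119 and 717), 49.9% with quantile normalization (840 and 842) and 0.56% under poly-A control scaling (24 and 4262 of 4286). The unadjusted count was 3367, 182 of 969 named probe sets were called, and the block gave 3662 (1642 and 2020), including all 1629. Groups did not overlap for 61.1%, against 33.3% for exchangeable arrays, and 231 changed 2-fold in all pairs, against 80 between replicate numbers. The count was 683 and 552 without control replicates 1 and 2, and 669 and 624 without UCZ replicates 1 and 2. Of 25 named genes called, 18 passed in each fit that left out 1 array. The other 7 (Lsi6, expB7, tha9, GLN6, hsp101, aldh2 and tub5) did not, and 7 missed the threshold under poly-A control scaling.

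The third comparison, GA3 against UCZ, set added gibberellin against the inhibitor of its synthesis. The glutathione S-transferase gene gst2 was 4.07-fold higher in GA3, at 2344 ± 14.6 against 569.3 ± 113 in UCZ (SD, n = 2; log2 2.02, SE 0.2, adjusted p = 0.0017). The phytase gene phytase1 was higher by 1.99 (SE 0.14, adjusted p = 0.00051), and the aquaporin gene pip2f by 1.98 (SE 0.15, adjusted p = 0.00068). The expansins expA3, expB4, expB6 and expB8 were higher by 1.70, 1.64, 1.60 and 1.57, with adjusted p between 0.00068 and 0.004. In the other direction, hsp18 was lower in GA3 by a log2 change of −2.97 (SE 0.33, adjusted p = 0.0025), at 141.2 ± 70.7 against 1160 ± 223.

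Also higher in GA3 were piip1 (1.79), mlg3 (1.74) and wip1 (1.66). Lower in GA3, next to hsp18f (−1.71) and betl4 (−1.56), were the glutamine synthetases gln1 (−1.25) and GLN6 (−1.09), aldh2 (−1.29), lpa1, which carries the synonym INO1 (−1.12), prpl35-1, a plastid ribosomal protein (−1.09), m21 (−1.08) and gpb1, the beta subunit of a G protein (−1.06). The adjusted p of all these genes lay between 0.00051 and 0.038. For gln1 the signal was 1229 ± 35.3 in GA3 and 2955 ± 321 in UCZ, and for gpb1 1732 ± 35.2 and 3639 ± 150.

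Of 9 expansins, 7 were higher in GA3, and all 9 when adjusted over the list alone, with a median of 1.05 (camera adjusted p = 7.72e-06; adjusted p = 0.277 with an estimated correlation). Of 14 genes on the list named tubulins and actins, which holds no actin, 6 were higher (9 when adjusted over the list alone). Among them were TUBB2 (1.19), tua6 (0.74) and tua5 (0.54). The list median was 0.47 (camera adjusted p = 0.000692, or 0.277 with an estimated correlation). Of 12 leaf photosynthesis genes, the other-tissue list, 6 were lower in GA3 (10 when adjusted over the list alone, 10 with the block), with a median of −0.44 that turned to 0.33, all 12 above 0, under poly-A control scaling (as deposited, camera adjusted p = 0.000101; adjusted p = 0.376 with an estimated correlation). Its members mdh6 and pep1, enzymes of C4 photosynthesis, and psbs1, a photosystem II protein, had changes of −0.71, −0.62 and −0.61, and these turned to 0.058, 0.15 and 0.16 under that scaling. Of 10 heat shock genes, 3 were lower, hsp18, hsp18f and hsp101 (4 when adjusted over the list alone), with a median of −0.20 that turned to 0.57 under poly-A control scaling (as deposited, camera adjusted p = 0.0175; adjusted p = 0.376 with an estimated correlation). Of 18 aquaporins, 8 were higher, among them tip2a (1.45) and pip2c (0.91), and tip4d was lower (−0.68), with the same counts when adjusted over the list alone and a median of 0.26 (camera adjusted p = 0.0418; adjusted p = 0.376 with an estimated correlation). Of 5 peroxidases and laccases, the peroxidases pox1 (0.86), ap1 (0.75) and PER42 (0.57) were higher, 3 also when adjusted over the list alone, with a median of 0.57 (camera adjusted p = 0.0418; adjusted p = 0.376 with an estimated correlation). Of 10 cellulose synthesis genes, 4 were higher (5 when adjusted over the list alone; cesa10 1.14, cesa11 1.03, CesA12 0.86), with a median of 0.27 (camera adjusted p = 0.0435; adjusted p = 0.376 with an estimated correlation). Under poly-A control scaling the median was 1.82 for expansins and 1.24 for the tubulin and actin list (13 higher). For aquaporins it was 1.03 (12 higher and none lower, so that the call of tip4d was lost). It was 1.34 for peroxidases and laccases (5 higher) and 1.04 for cellulose synthesis (9 higher). Correcting the lists moved cellulose synthesis and aquaporins to an adjusted p of 0.0644. Leaving out 1 array ended the call of cellulose synthesis in 5 of 6 fits (adjusted p = 0.0502 to 0.0707), of the peroxidases in 3 (0.0542 to 0.0607) and of aquaporins in 1 (0.0573). The reproductive gene M2 was higher in GA3 by 1.23 (adjusted p = 0.0054), while pht1, gz27 and m19, at −0.095, −0.23 and −0.37, were not called.

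In all, 1474 probe sets passed, 805 higher and 669 lower in GA3 (54.6% higher, of which 262 and 107 at least 2-fold). The higher share was 40.1% with median centring (617 and 920) and 99.7% under poly-A control scaling (6636 and 21 of 6657). The unadjusted count was 3101, 179 of 969 named probe sets were called, and the block gave 3271 (1800 and 1471), including all 1474. Groups did not overlap for 57.5%, against 33.3% for exchangeable arrays, and 199 changed 2-fold in all pairs, against 86 between replicate numbers. The count was 738 and 714 without GA3 replicates 1 and 2, and 730 and 541 without UCZ replicates 1 and 2. Of 35 named genes called, 26 passed in each fit that left out 1 array and 11 missed the threshold under poly-A control scaling. The 9 others were GLN6, CesA12, hsp101, pep1, psbs1, PER42, ap1, pox1 and tua5. No list called in any comparison passed with an estimated correlation. That test has 3 residual degrees of freedom and little power, so these misses do not count against the lists. All lists called passed with fry, which tests whether the genes of a list move on balance in one direction. It does not compare them with other genes.

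**Figure D2:**
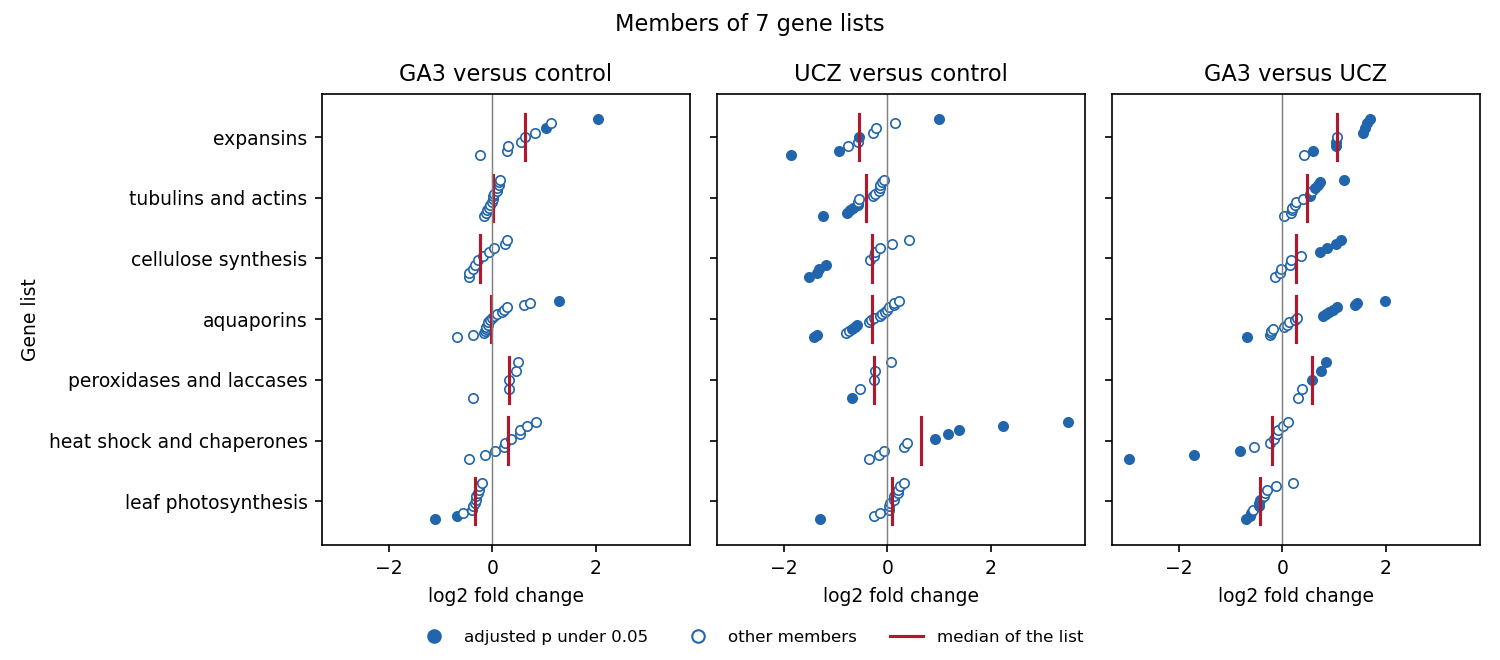
Log2 fold change (horizontal axis) of each measured member of 7 gene lists (vertical axis) in the 3 comparisons. Filled points are members at an adjusted p under 0.05, and vertical lines are the list medians. The list labelled tubulins and actins holds no actin gene. Expansins had a median of 0.625 in GA3 versus control and 1.05 in GA3 versus UCZ, where leaf photosynthesis (−0.44) and heat shock genes (−0.20) lay below 0, medians that turned to 0.33 and 0.57 under poly-A control scaling; the heat shock median of 0.65 in UCZ versus control became 0.012 under it.

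Of the gibberellin genes, an1, an ent-copalyl diphosphate synthase at the start of the pathway, had a signal of 486.4 ± 37.6 in control, 479 ± 28.9 in GA3 and 369.4 ± 12.9 in UCZ (SD, n = 2). Its log2 change was −0.021 in GA3 versus control (adjusted p = 0.98), −0.38 in UCZ versus control (adjusted p = 0.096; 0.026 with the block) and 0.36 in GA3 versus UCZ (adjusted p = 0.12; 0.036 with the block), and the first turned to 0.11 under poly-A control scaling. Under that scaling the changes involving UCZ were −1.02 and 1.13, both past the threshold. The dimmer CPPS2, which carries the synonym an2 and the same enzyme name but is known for defence diterpenoids and was put among these genes by its name, and d3, the cytochrome P450 of the dwarf3 locus, fell below the intensity filter and were tested without it over 17621 probe sets. CPPS2 fell from 314.1 ± 25.9 in control to 29.72 ± 3.76 in GA3 (log2 −2.85, SE 0.18, adjusted p = 0.0017) and to 81.22 ± 7.85 in UCZ (−1.76, adjusted p = 0.0036). It was lower in GA3 than in UCZ by a log2 change of −1.09 (adjusted p = 0.017). The signal of d3 was 86.36 ± 15.8, 110.8 ± 17.8 and 77.16 ± 7.33 in control, GA3 and UCZ, with changes of 0.31 (adjusted p = 0.72), −0.13 (0.77) and 0.44 (0.28) in the 3 comparisons.

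A last comparison asked whether GA3 and UCZ moved genes in opposite directions. Few did: 10 probe sets rose in GA3 and fell in UCZ, among them phytase1, pip2f and expB6, and 2 fell in GA3 and rose in UCZ, of which gpb1 was named (−0.68 and 0.39, but −0.55 and −0.25 under poly-A control scaling, neither called). Far more fell under both treatments, 68, including pr5, prp4, chn1, me3, sps1, f3h, AGA3b, nthr3 and aprl1, and 15 rose under both, including expB7 and pdc3. Neither of these passed in both comparisons under poly-A control scaling (expB7 0.36 in UCZ, adjusted p = 0.3; pdc3 0.84 in GA3, adjusted p = 0.45), expB7 in UCZ also missed the threshold in 2 of 6 fits that left out 1 array, and pdc3 in GA3 in all 6. Of the 9 genes listed as falling under both, pr5, prp4 and sps1 were still called in both under that scaling. For sps1 the signal was 115.8 ± 12.1 in GA3 and 117.9 ± 24.3 in UCZ against 359.5 ± 3.53 in control. Independent lists of the same sizes would share 3.28 higher in both, 7.98 lower in both, 4.57 higher in GA3 and lower in UCZ, and 5.73 in the reverse direction. With the block the 4 counts were 137, 334, 63 and 47, in that order, and under poly-A control scaling they were 2, 34, 20 and 0. Unchanged groups set against the same controls gave means of 0.18, 0.08, 0 and 0 in 100 simulations. Independent lists leave out the shared controls and the simulations leave out the effects.

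Across the 10573 probe sets the log2 changes of the 2 treatments against control correlated at r = 0.399, with a covariance of 0.0547. Both comparisons share the control arrays. Unchanged groups set against those controls in 100 simulations gave r = 0.501 and a covariance of 0.0227. With the spread of the blocked fit these were 0.5 and 0.00901. The shared controls fix the simulated r near 0.5 whatever the spread, so it is no benchmark for the measured r. With no control array in common, pairing GA3 replicate 1 with UCZ replicate 2 and the reverse, r was 0.24 and 0.26 and the covariance 0.0405 and 0.0412. The controls could not be split into parts of 2 arrays, so part of the excess over independent lists may come from the shared controls.

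**Figure D3:**
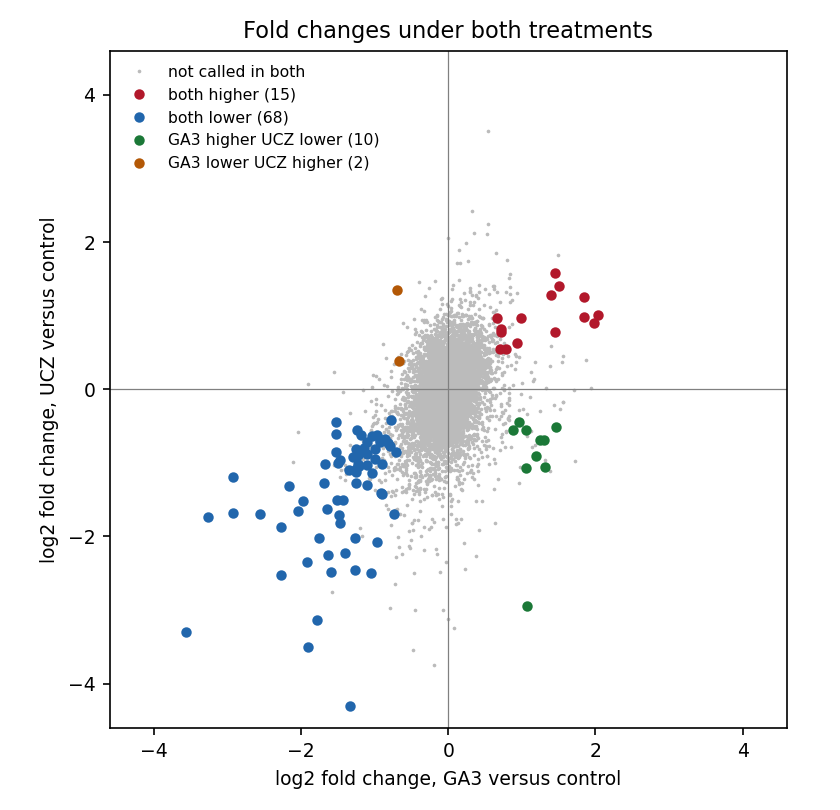
Log2 fold change in UCZ versus control (vertical axis) against that in GA3 versus control (horizontal axis) for each of 10573 probe sets, with colours for those called in both comparisons. Of the called points, 68 lie at the lower left, 15 in the upper right, 10 in the lower right and 2 in the upper left.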

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

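All tests of explanations here were chosen after the result was seen. The probe sets of the bacterial poly-A control transcripts, which enter none of the comparisons between groups, were brighter on both UCZ arrays than on both control arrays. The log2 difference was 0.618 for Dap, 0.667 for Lys, 0.698 for Phe and 0.58 for Thr, while GA3 minus control was −0.13, −0.064, −0.12 and −0.21.

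The tables argue against brighter hybridization or scanning of the UCZ arrays, since the hybridization controls differed by 0.161 on average, with 0.132 and 0.19 in the replicates against 0.616 and 0.665 for the poly-A controls. The rise differed between replicates by 0.0486, less than the SD of the 12 probe sets (0.186 and 0.141). That SD is a spread among probe sets and not between preparations, so the comparison decides nothing. A difference in the amount of control added per amount of total RNA, systematic or not, stays open. Less maize messenger RNA per amount of total RNA in the UCZ samples, a biological candidate explanation, would put the median log2 change of all probe sets at −0.667. These last explanations cannot be told apart, because each gives the same values on the arrays and the sources used here hold no measure of the amount added. Under the second, most transcripts would be lower in UCZ per amount of total RNA, while the order of the changes among genes would stay as given.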

How the results depend on the processing

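Poly-A control scaling, the corrected lists and the comparisons without a shared control were chosen after the data were seen, and the other alternatives before. Of 84 named values, 60 of the 61 still measured in the brightest 40% of probe sets, 82 with median centring, 84 with quantile normalization, 84 with 1 added, 83 with 64 added, 78 with no filter, 80 without a trend, 82 with the robust prior and 80 with only the 2 groups compared kept their direction and side of the threshold. Poly-A control scaling kept 53, with 24 calls lost at an unchanged sign, 3 gained and 4 signs turned. Among the calls lost in GA3 versus control, cpi2 and pdc3 had larger changes under it (0.752 and 0.842, against 0.623 and 0.714). The rest there had smaller ones, such as chn1 (−1.04 against −1.17). Differences of the poly-A controls between replicates add to the spread in that fit, so these losses do not come from the shift alone. Of the values whose sign turned, pep1, psbs1 and mdh6 in GA3 versus UCZ also lost their calls. Leaving out 1 array kept 63 to 70 and lost 14 to 20, which follows at least in part from fewer arrays, with the lone array of a group assumed to vary like the others. The signs that turned under poly-A control scaling were those of an1 in GA3 versus control (0.108) and, in GA3 versus UCZ, pep1 (0.149), psbs1 (0.162) and mdh6 (0.0582), where the shift of all values by the scaling is the cause. Calls lost without 1 array may also come from the difference between replicate numbers, which enters the changes of the group left with 1 number. Without 1 array, an1 in GA3 versus control ran from −0.097 to 0.0559, with 0.0391 without GA3 replicate 1 and 0.0559 without control replicate 2, all within its SE of 0.13. The robust prior was not run for gene lists, since camera has no such option, nor was the F test with only 2 groups.

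The replicate block, which uses the pairing, gave 866, 3662 and 3271 probe sets for GA3 versus control, UCZ versus control and GA3 versus UCZ, and 4048 for the F test. With quantile normalization these were 859, 3535, 3052 and 3864, with 5 lists in GA3 versus control, 5 in UCZ versus control and 5 in GA3 versus UCZ, where cellulose synthesis (0.052) and the peroxidases (0.0652) were lost. Among the named values the block alone brought past the threshold only expA3 (adjusted p = 0.00027) and pep1 (0.0021) in GA3 versus control and an1 in UCZ versus control (0.026) and GA3 versus UCZ (0.036). Among lists it added lignin in GA3 versus control (0.0493) and aquaporins in UCZ versus control (0.0473), at 0.48 and 0.656 with an estimated correlation. It changed no other call among the 84 named values and the lists. Outside them it brought m19 (adjusted p = 0.0056) and M2 (0.011) past the threshold in GA3 versus control, and asn1 by its dimmer probe set in UCZ versus control (0.0046), and it raised most counts of called list members given in the text.

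Poly-A control scaling gave 78, 4286 and 6657 probe sets, and 5507 in the F test. A threshold of 0.10 gave 283, 2565, 2234 and 2509 in the same order. The brightest 40% gave 78 in GA3 versus control, 37, 143 and 116 probe sets 2-fold in all pairs, a correlation of 0.329 between the treatments, and 4 lists in GA3 versus UCZ, where fewer genes are tested. No filter gave a correlation of 0.452 and 126 probe sets 2-fold in all pairs in GA3 versus control, and a 1.5-fold rule gave 198, 794 and 754. The correlation was 0.412 with quantile normalization, and 0.24 and 0.26 with no control shared. Lists called, against 2, 3 and 7, were 0, 0 and 0 with an estimated correlation in camera (1, 1 and 2 of 22 at an unadjusted p under 0.05), 4 and 12 with fry for the comparisons against control, 4 in GA3 versus control with only the 2 groups and 4 with the corrected lists, which put pr5 and prp4, 2 of the largest named falls, into the defence list. In UCZ versus control they were 5 with quantile normalization, 5 with 64 added and 6 with all probe sets of a gene. Camera with an estimated correlation rests on 3 residual degrees of freedom, which limits its power. Apart from that, the stricter or looser thresholds, the smaller sets of probe sets and the scalings, the cause was not tested.

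Leaving out each array in turn gave 51 to 112 probe sets in GA3 versus control, 552 to 1546 in UCZ versus control, 541 to 1154 in GA3 versus UCZ and 584 to 1277 in the F test, a correlation of 0.303 to 0.552, and 2 to 5, 3 to 5 and 4 to 7 lists. Of the 12 list calls, 12 kept their side with median centring, quantile normalization, other added values, no filter and the block, 10 with the block and quantile normalization, without a trend or with corrected lists, 8 in the brightest 40% and 9 to 12 without 1 array. The list test was not run under poly-A control scaling. The lists lost were those of GA3 versus UCZ for aquaporins, cellulose synthesis, peroxidases and, in the brightest 40%, heat shock in 2 comparisons. The filter kept 10573 of 17621 probe sets, and the genes below it were tested only without it.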

Other observations

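All tests of explanations here were chosen after the results were seen, and so were the genes and lists named. Glutathione S-transferases, which conjugate glutathione to foreign and reactive compounds, split in UCZ versus control: of 24 measured genes 2 rose and 8 fell, and 14 did not pass, against 3 and 8 when adjusted over the list alone and 4 and 10 with the block (camera adjusted p = 0.516). The signal of gst2 fell from 1206 ± 295 to 569.3 ± 113 (SD, n = 2; log2 −1.05, adjusted p = 0.014), while gst10 and gst19 rose by 0.73 and 0.88. Under poly-A control scaling none rose and 13 fell. In GA3 versus UCZ 8 were higher, including gst11 (1.36), and gst10 and gst19 were lower (camera adjusted p = 0.197), while 16 were higher and none lower under that scaling.

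Of 12 genes of amino acid remobilisation and proteolysis, 2 rose and 2 fell in UCZ versus control and 8 did not pass (camera adjusted p = 0.976). With the block 2 rose and 4 fell, as when adjusted over the list alone, while none rose and 5 fell under poly-A control scaling. The asparagine synthetase asn1 fell from 3213 ± 113 to 1367 ± 103 (log2 −1.22, adjusted p = 0.00098) and the glutamate dehydrogenase gdh1 from 805.1 ± 11.7 to 349 ± 48 (−1.18, adjusted p = 0.0031), while the glutamine synthetases gln1 and GLN6 rose by 0.92 and 1.31. A dimmer probe set of asn1 went the same way and passed only with the block (adjusted p = 0.0046). The vacuolar invertase ivr2 fell from 3125 ± 503 to 1281 ± 278 (−1.28) and the cell wall invertase incw1 rose from 154.2 ± 4.25 to 309 ± 43.8 (0.93); of the 5 genes of their list (camera adjusted p = 0.707) none rose and 2 fell under poly-A control scaling. The fermentation genes pdc3, adh1 and adh2 rose by 0.82, 0.59 and 0.57, and the glyceraldehyde phosphate dehydrogenases gpc3 and gpc4 of the same list had changes of −0.72 and −1.18 (camera adjusted p = 0.356 for the list of 7). Under poly-A control scaling none of these 7 rose and 2 fell, with a median of −0.37 in place of 0.27. In the cell cycle list the kinesin genes krp6 (−1.24) and kin11 (−0.65) and the replication clamp pcna1 (−0.88) fell, 3 of 15 (camera adjusted p = 0.0778), against 4 that fell and 1 that rose with the block and 11 that fell under poly-A control scaling. The probe sets of pgr5 disagreed: one fell from 657.7 ± 30.4 in control to 181.9 ± 39 in GA3 and 60.37 ± 5.84 in UCZ, and the other had signals of 726.6 ± 126, 621.4 ± 79.7 and 714 ± 99.7.

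The log2 changes in GA3 and UCZ were positively correlated across probe sets (r = 0.399, covariance 0.0547), although the treatments add gibberellin and inhibit its synthesis. The tables argue against the shared control arrays as the whole cause, since the covariance was 0.0405 and 0.0412 with no control array in common. A handling step or solvent common to both treatments and a response of the plant to either treatment cannot be told apart. No array had the step without a treatment. The actin 3′/5′ ratio was also higher in GA3 (4.64 and 3.4) and UCZ (4.14 and 3.11) than in control (3.57 and 2.76). RNA quality was not tested for this pattern and stays open. In all, 68 probe sets fell under both, a count to which the shared controls may add. The ent-copalyl diphosphate synthase CPPS2, tested without the filter, was also lower under both (−2.85 and −1.76).

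Of 10 heat shock genes, 5 were called higher in UCZ versus control, hsp18, hsp18f, hsp22, hsp101 and hsp18a. Names do not give the likeness of sequences. The test of names covers only cross-hybridization among the hsp18 names, and cross-hybridization with hsp22 stays open. Cross-hybridization among hsp18 names as the whole cause under the deposited scaling is argued against by 2 called members with other names, hsp22, which passed in each fit that left out 1 array, and hsp101, which missed the threshold in 4 of 6. Poly-A control scaling shifts all genes alike, so its median of 0.0117 for the 10 genes, in place of 0.652, decides nothing about the scaling of the deposited signals; hsp18 and hsp18f still passed under it, while hsp22 and hsp101 went from 1.39 and 1.18 to 0.751 and 0.539 and did not. RNA quality stays open: the median of the 10 genes in GA3 versus UCZ was −0.204, too small to decide, with an actin 3′/5′ ratio higher in GA3 (4.64 and 3.4) than in UCZ (4.14 and 3.11). A stress response to UCZ and a difference in handling of the UCZ plants were not tested.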
